A study of Mus musculus with 16 samples.

How the data were processed

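The deposited count matrix holds raw UMI counts (counts) for 32288 features and 22790 barcodes, with 132622698 entries and 1036170010 UMIs. The authors' per-cell annotation covers 22602 of these barcodes, and 188 barcodes without annotation were not used. Total UMIs per cell in the annotation are counts as deposited and equal the column sums of the matrix. The deposited mitochondrial share per cell is in percent and equals the share computed from the matrix. The GFP score is a unitless number per cell in the authors' annotation, and how it was computed is not stated per the labels. The remaining columns used are deposited labels without a unit, namely library letter with population number, population, age, sorted CD150 gate, GFP group, megakaryocyte progenitor subgroup and cell type. A further 7 annotation columns were not used here, among them the antibody and oligo count columns and the MHC class II column. Values per 1000000 UMIs (CPM) are computed from summed counts.

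Per the labels' protocols, c-Kit-enriched marrow of hind legs was stained, and live lineage-negative c-Kit+ cells were sorted into CD150- and CD150+ fractions through touching gates. The 4 sorted populations (young or old, CD150- or CD150+) were each divided into 3 aliquots with 1 multiplexing oligo each, 12 in all. Aliquots were combined in equal numbers where possible, and the pool was divided into 2 replicates for 10x Chromium 3' libraries (chemistry v3.1). Per the same protocols there were 2 independent experiments, with 50000 read pairs per cell aimed at for expression and 5000 for oligos. Per the submitters' processing notes, reads were processed with Cell Ranger (version not stated) on mm10 with reporter transgenes added. Cells under 200 genes and genes in fewer than 3 cells were removed by the authors, and 13 cells without Kit and 157 doublets (DoubletDetection 2.4.0, p threshold 1e-16, voter threshold 0.5) were also removed. Counts were then scaled by the authors to 10000 per cell and logged with a pseudocount of 1, steps that are not applied in the deposited matrix.

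The matrix differs from these notes in some counts. It has 22984 features with a UMI in at least 3 barcodes, where 22870 are stated. The lowest number of genes in a barcode is 503. The notes' removals add up to 170 cells, against 188 without annotation. Among annotated cells, 2315 have no Kit UMI in the deposited counts. Mitochondrial transcripts make up 3.02 % of all UMIs, ribosomal protein transcripts 32.1 % and Malat1 0.253 %, and all were kept in the main analysis. Of the transgenes, Egfp has 836700 UMIs, Tdtom 413 and Crer 0.

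The replicate unit is the library, A to D, taken from the deposited cell labels. The annotation does not say which libraries share an experiment. Each letter matches more than 1 of the 16 samples of the series, so cells were not assigned to single samples. Cells annotated per library number 6598 in A, 6664 in B, 4109 in C and 5231 in D. Median UMIs per cell are 42620.5, 45568, 47675 and 42910, from library totals of 278715383, 300798647, 204776240 and 236080819 UMIs. Cell types are the authors' 21 annotated types, with the reporter classes of megakaryocyte progenitors (MkP) merged. The number of mice behind each pool is not stated, and aliquots of a library were summed. P-values therefore measure spread between libraries, part of which may be technical, and do not measure spread between mice.

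Raw counts were summed per library, age, gate and cell type, and sums under 20 cells were left out. Sums of the reporter classes of MkP took both gates together. Genes were tested with edgeR 4.0.16 quasi-likelihood (TMM, filterByExpr, library as block, sorted population as factor), with limma 3.58.1 for gene lists. P-values were adjusted by Benjamini-Hochberg (BH), and an adjusted p under 0.05 is a call. Old against young was tested for every type with sums in at least 2 libraries per age, averaged over gates present at both ages. That gave 17 types, MkP among them. CD150+ against CD150- was tested in the 4 types with enough cells in both gates, averaged over ages. Shares of cell types were tested by edgeR quasi-likelihood on cell numbers within each gate, with the total of the gate as library size and at least 10 cells of the type per gate. Errors beside log2 values are standard errors of the fit, and those beside means are standard deviations over libraries.

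Fixed lists of genes, 29 in all, were tested with fry on the same fits, in 1 direction and for either direction, and adjusted over lists. Camera with a preset correlation of 0.01 and with an estimated correlation was the alternative. Named genes follow a fixed rule: the largest changes among called genes with at least 20 CPM on average and the same direction in every library, 12 per direction in main comparisons, 3 in other types and 5 for differences of effects. Kit, Slamf1, Flt3, the transgenes and up to 4 members of a fixed list per direction may be named besides. The rule leaves out gene models without a symbol of their own and receptor segments. A few genes that meet it are not reported here.

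Reporter shares were computed after thinning every cell to 8000 UMIs, leaving shallower cells out, and compared as logits per library by exact sign flips, whose smallest possible p with 4 libraries is 0.125. The tests, the thresholds on cells per sum and adjusted p, the lists and the first set of alternatives were fixed before the data were examined. The number of UMIs thinned to and the lowest number of cells for a share test were set once depths and cell numbers were known. The settings to be compared with them are DESeq2 1.42.0, no filter on low counts, no replicate block, each library left out, equal numbers of cells per sum, TMM scaling of cell numbers, gates together, at least 2 UMIs for the reporter, no thinning and camera. Sums per aliquot, also planned, were not run because the annotation does not give the aliquot.

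Further comparisons and alternatives were chosen after seeing the data. These are the authors' reporter classes of MkP compared with each other, libraries summed in 2 pairs (A with B, C with D), each pair alone, counts without mitochondrial, ribosomal protein and Malat1 transcripts, and the difference of the age effect between MkP and each of 4 other types. The planned fit for haematopoietic stem cells (HSC), and with it the planned difference between MkP and HSC, could not be run, because no young sum reaches 20 cells. A small fit on CD150+ sums of at least 5 cells from A and B was added in its place. Gene positions are from GENCODE vM21 (GRCm38, the assembly also named mm10), which may not be the annotation the authors used, and 198 of 200 genes looked up were found by symbol.

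Residuals of sums from the same library were compared to see whether blocking by library fits the values, over 30 groups of 4 sums and 6063 genes. The median correlation is 0.183 within a library, 0.0709 with the other library of the pair and -0.124 across pairs. Per library it is 0.216 in A, 0.174 in B, 0.132 in C and 0.197 in D. The grouping of A with B and C with D rests on these values and not on a label.

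Each kind of fit was tried on simulated negative binomial counts, drawn from fitted means without the tested difference, with changes planted in 200 genes. For old against young MkP (10894 genes), 68.7 % of planted 1.5-fold changes were recovered, 74.6 % of 2-fold and 98.5 % of 4-fold, with 15 false calls. For Tom+ against GFP+ MkP (10480 genes) the shares were 64.2 %, 85.1 % and 98.5 %, with 7 false calls, and for old against young GFP+ MkP 70.1 %, 86.6 % and 93.9 %, with 6. Early erythroid progenitor A (8741 genes) gave 76.1 %, 89.6 % and 98.5 %, with 11, and Lymphoid B (9069 genes) gave 43.3 %, 86.6 % and 93.9 %, with 3. The gate comparison in early erythroid progenitor A gave 80.6 %, 94.0 % and 97.0 %, with 16. The difference between MkP and megakaryocyte-erythroid progenitors (MEP, 10396 genes) gave 22.4 %, 62.7 % and 90.9 %, with 7. A planted 3-fold change in the share of MkP was called in 47 of 50 simulations.

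Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3, data.table package 1.17.8 and the packages above, with seed 1 for random draws and seed 7 for the simulations.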

Results

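Marrow progenitor cells of young and old mice were profiled as single cells by 10x 3' sequencing of lineage-negative c-Kit+ cells sorted as CD150- or CD150+. The mice carry a FlkSwitch reporter, in which a cell changes from Tom to GFP once it or an ancestor has expressed Flt3. Each of 4 libraries (A to D) pools the 4 sorted populations, so old and young cells share a library. Annotated cells number 6598, 6664, 4109 and 5231, with median UMIs per cell of 42620.5, 45568, 47675 and 42910. The authors name 21 cell types, and their names are used throughout. The library is the unit of replication (n = 4 per group, fewer in some cell types), because the annotation does not name the experiment, and the number of mice per pool is not stated. Libraries fall into A with B and C with D by their values. Per the protocols each pool was divided into 2 replicates in 2 independent experiments, so if these pairs are such divided pools, n = 4 overstates the replication and the experiments number 2. Values with libraries summed in these 2 pairs are therefore given beside the results for shares and for MkP genes. For the other types, the gate and differences of effects they are given mostly as totals, near the end.

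Haematopoietic stem cells (HSC) and megakaryocyte progenitors (MkP) took up more of the old CD150+ gate. Early erythroid progenitors A and B and Ery C cells took up less, while Ery A, Ery B and Ery D cells were not called. HSC made up 6.04 ± 2.63 % of old and 0.304 ± 0.134 % of young CD150+ cells (log2 ratio 4.25 ± 0.29, adjusted p = 3.4e-05, higher in 4 of 4 libraries). MkP rose from 10.4 ± 3.09 % to 34.03 ± 9.98 % (log2 1.74 ± 0.38, adjusted p = 0.0153, higher in 4 of 4). The GFP-negative class of MkP, which the authors call Tom+ MkP, rose from 1.16 ± 1.22 % to 16.9 ± 5.87 % (log2 4.38 ± 0.96, adjusted p = 0.0366, 4 of 4). GFP+ MkP went from 9.26 ± 1.96 % to 17.2 ± 4.26 %, a difference that was not called (log2 0.90, adjusted p = 0.0991). Ery C cells fell (log2 -3.21 ± 0.68, adjusted p = 0.0153, lower in 3 of 4). That fall rests on A and B, since the gate held 1 old and 1 young Ery C cell in C and only 2 young ones in D. Early erythroid progenitors B fell from 36.4 ± 1.88 % to 17.9 ± 9.67 % (log2 -1.20, adjusted p = 0.0497), and early erythroid progenitors A from 15.5 ± 4.71 % to 8.12 ± 0.48 % (log2 -0.92, adjusted p = 0.0497), both lower in 4 of 4. Tests are edgeR quasi-likelihood on cell numbers with BH over the types of the gate.

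The size of the MkP rise differed between the library pairs. Old MkP shares were 44.5 % in A, 40.5 % in B, 26.9 % in C and 24.2 % in D, against 9.14 %, 6.84 %, 13.9 % and 11.8 % in the young. The log2 ratio was 2.42 within A and B and 0.995 within C and D (1.71, adjusted p = 0.316, with libraries summed in 2 pairs). For Tom+ MkP it was 6.63 within A and B and 2.51 within C and D (adjusted p = 0.0598). HSC held with pairs (adjusted p = 0.0021 by edgeR quasi-likelihood), and so did Tom+ MkP (adjusted p = 0.0494). Ery C did not (adjusted p = 0.0997), nor did early erythroid progenitors A and B (adjusted p = 0.628 each). Leaving out any 1 library left only 1 type called by edgeR quasi-likelihood, and MkP then gave log2 1.53 without A, 1.45 without B, 1.99 without C and 1.96 without D (adjusted p = 0.178, 0.104, 0.0563 and 0.0697). These are shares of sorted cells, and a rise of 1 type lowers the others.

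**Figure D1:**
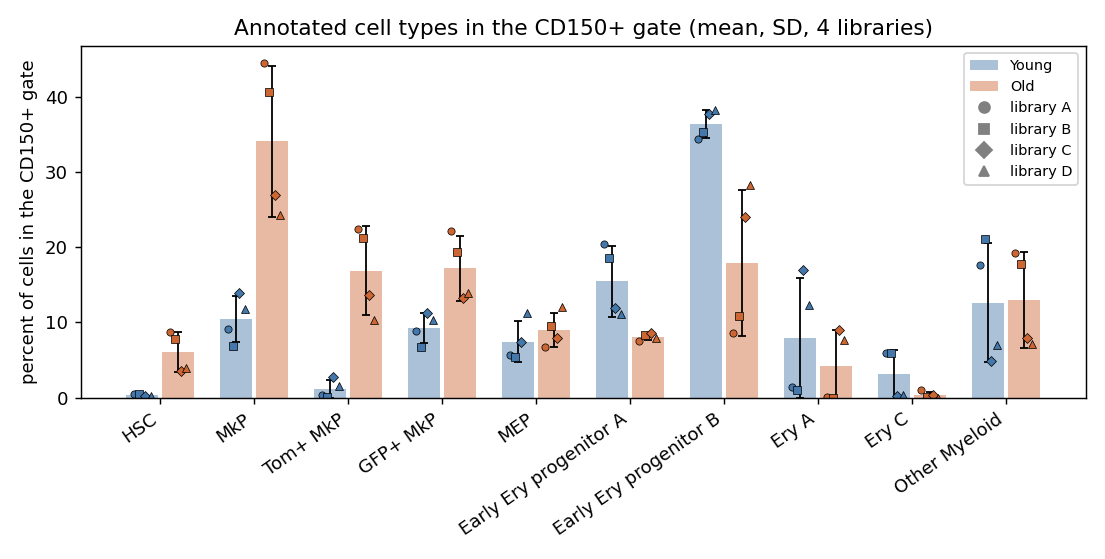
Share of annotated cell types among CD150+ cells (percent of the gate), 1 point per library and age. Points for MkP lie at 24.2 to 44.5 % in old and 6.84 to 13.9 % in young.

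In the CD150- gate no type passed the threshold, though several lay close to it. HSC (log2 2.85), early erythroid progenitors B (-0.94) and Lymphoid B cells (0.74) each had an adjusted p of 0.053 by edgeR quasi-likelihood, with the same direction in 4 of 4 libraries. The HSC ratio rests on only 3 young cells against 26 old ones, over all libraries. Within A and B alone 12 types passed, and within C and D alone 9. If a pair is 1 divided pool, those tests measure only the spread of the division and add no replication. Of 21 types tested, 9 had an unadjusted p under 0.05, MPP C and Ery C among them, and no other tool was run on shares. GMP/Neut progenitors A show the gap between the pairs, with log2 1.60 in A and B and 0.29 in C and D.

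Cells without reporter transcript were more frequent among old than among young MkP in every library. With each cell thinned to 8000 UMIs, 42.2 ± 4.58 % of old and 8.16 ± 7.70 % of young MkP had no Egfp UMI (logit difference of detection -2.47 ± 1.17, 4 of 4 libraries, exact p = 0.125, the smallest possible with n = 4). Without thinning the shares were 30.9 ± 7.17 % and 7.78 ± 7.15 %, and thinning left out 13 old and 4 young cells. The authors' own GFP group gave 45.4 % and 9.68 %. Other types, HSC aside, had fewer such cells, for instance 13.5 % of old and 5.14 % of young megakaryocyte-erythroid progenitors (MEP), 10.2 % and 4.75 % of early erythroid progenitors B and 4.61 % and 1.79 % of GMP/Neut progenitors A. Among HSC, with the cells of all libraries pooled after thinning, 63.25 % of 166 old and 33.33 % of 15 young cells had no Egfp UMI. The shares with one were 36.75 % (95 % limits 29.41 to 44.57) and 66.67 % (38.38 to 88.18), limits that cover counting error only. Median depth of CD150+ MkP was 24399 UMIs in old and 25624.5 in young.

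The GFP classes are well separated in Egfp counts, while Tdtom is read only faintly. GFP+ MkP carry a median of 21 Egfp UMIs in old and 25 in young, and GFP-negative MkP carry 0. The authors' score has its limit between 1.343 and 1.344, and 16 of 866 old and 7 of 400 young MkP lie within 0.25 of it. Of the 402 GFP-negative old MkP, 254 have no Egfp UMI, as do 26 of the 32 young ones. Tdtom was found in 13.4 % of 1450 GFP-negative cells of all types and in 0.785 % of 21152 GFP+ cells, or 4.34 against 0.182 UMIs per 1000000.

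**Figure D2:**
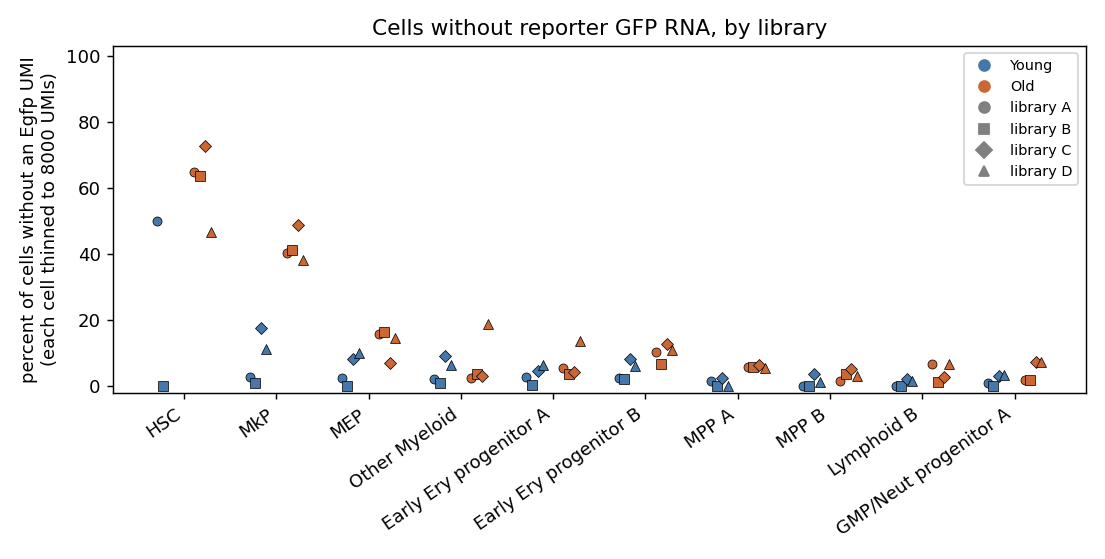
Percent of cells without an Egfp UMI after thinning to 8000 UMIs, by cell type, age and library. MkP reach a mean of 42.2 % in old against 8.16 % in young.

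Old MkP carried more transcripts of the nuclear receptors Rorb and Rora, the scramblase Plscr2, the caspase Casp12 and the retinaldehyde dehydrogenase Aldh1a1 than young MkP. Aldh1a1 rose from 15.5 ± 1.9 to 102 ± 8.3 CPM (log2 2.71 ± 0.10, adjusted p = 1e-13). Plscr2 rose from 0.943 to 40.6 CPM (log2 5.38 ± 0.23, adjusted p = 5.1e-13), and Rorb from 0.618 to 40.1 CPM (log2 6.04 ± 0.42, or 5.43 without library B and 7.23 without D). The young levels of these genes are near zero, so their folds are loose. Other rises were Casp12 (3.18 ± 0.21), Rora (2.77 ± 0.15), B3galt1 (2.64 ± 0.21), Phactr1 (2.61 ± 0.16), the stress regulator Nupr1 (2.44 ± 0.18), Magi2 (2.36 ± 0.27), the growth factor Pdgfd (2.26 ± 0.15), Clca3a1 (2.23 ± 0.12) and S100a6 (2.13 ± 0.14). Cd48, a surface receptor of the SLAM family, fell from 61.2 to 19.3 CPM (-1.79 ± 0.14, adjusted p = 6e-09). Cers6 (-1.66 ± 0.17), Plxdc2 (-1.55 ± 0.14), the galectin gene Lgals1 (-1.31 ± 0.14), Plac8 (-1.25 ± 0.08), Usp40 (-1.12 ± 0.15), Hsph1 (-1.10 ± 0.13), Samd14 (-1.04 ± 0.11), St8sia6 (-1.02 ± 0.16), Atp13a3 (-1.02 ± 0.14) and Ubash3a (-1.002 ± 0.11) fell as well. Egfp fell from 1190 ± 95.1 to 542 ± 17.5 CPM (-1.13 ± 0.05, adjusted p = 3.9e-13). Kit rose (0.54 ± 0.07, adjusted p = 2.8e-05), Flt3 was not called (0.26 ± 0.32, adjusted p = 0.70), and each gene of this paragraph that was called kept its direction in 4 of 4 libraries.

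Slamf1, which encodes CD150, was close to the threshold in old MkP (log2 0.48 ± 0.15, adjusted p = 0.042). It lost its call without A (0.37, adjusted p = 0.23), without B (0.46, adjusted p = 0.12) and without C (0.48, adjusted p = 0.064). In all, 1216 of 10894 genes were called by edgeR quasi-likelihood with BH, 648 higher and 568 lower in old CD150+ MkP, from 786 old and 366 young cells in 4 sums each. DESeq2 called 474, the fit without the block 508, equal numbers of cells per sum 199, and libraries summed in 2 pairs 1358. Without A 646 were called and without B 709, against 1158 without C and 1044 without D. Within A and B alone there were 1283 calls and within C and D alone 498. Of the genes tested in both pairs, 207 were higher and 93 lower in each, where 20.5 and 9.27 would arise by chance, and 5 went opposite ways.

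**Figure D3:**
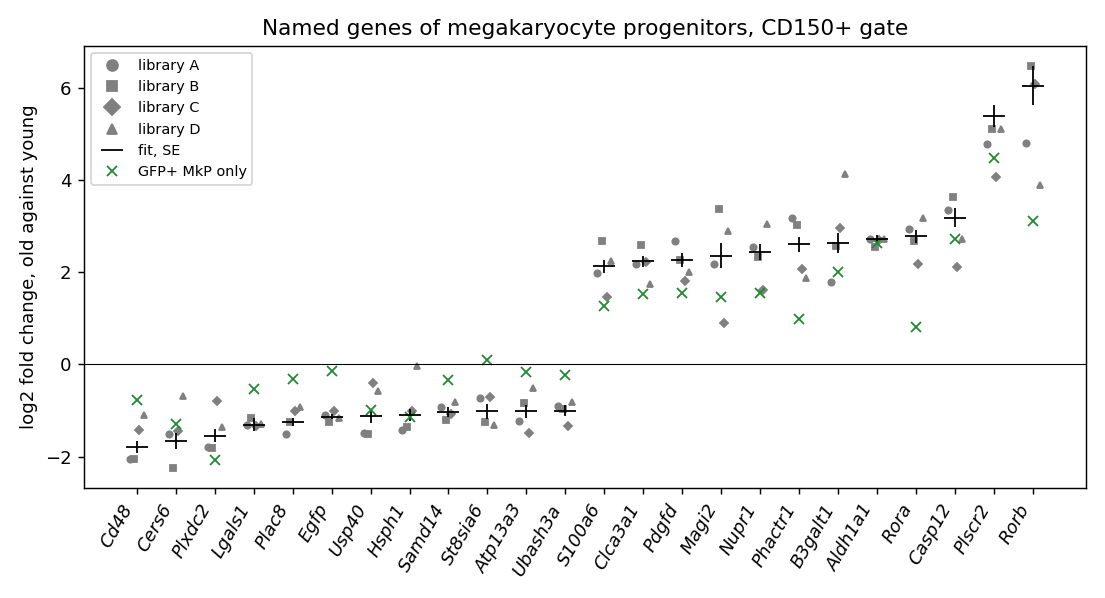
Log2 ratio of old to young for the named genes in CD150+ MkP, 1 point per library with the fitted value and its standard error. Plscr2 (5.38) and Cd48 (-1.79) show the size of the rises and falls.

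Markers of HSC and genes of a fixed HSC ageing signature rose in old MkP. Of 13 measured HSC markers 10 rose and 0 fell (11 and 0 adjusted over the list alone), among them Mecom (1.34 ± 0.08), Pdzk1ip1 (0.83 ± 0.09) and Ifitm1 (0.71 ± 0.09). Of 23 measured ageing genes 19 rose and 0 fell (19 and 0 adjusted over the list alone), among them Selp (1.36 ± 0.12), Clu (1.31 ± 0.14), Mmrn1 (1.16 ± 0.09) and Vwf (0.54 ± 0.07), besides Aldh1a1, Nupr1 and Plscr2. Both lists had a fry adjusted p of 0.0121, which does not hold with an estimated correlation between genes (0.0669 each). Of 12 measured MkP markers 4 rose, such as Vwf and Pf4, and 1 fell (Gp5, -0.35 ± 0.08), and of the 4 only Vwf kept its call without A. That list was not called in 1 direction (adjusted p = 0.122) but was in either (0.0014). Of 26 platelet receptor and signalling genes 5 rose and 4 fell, Gp5, Fcer1g (-0.70 ± 0.12) and F2rl2 (-0.38 ± 0.08) among the latter (adjusted p = 0.681, either direction 0.0023). Of 15 granule genes 6 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.0166, or 0.130 with an estimated correlation). Thbs1, which encodes thrombospondin, was among the lower ones, at 0.793 against 7.002 CPM.

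Single chaperone and mitochondrial genes fell in old MkP, while no list call of this paragraph holds with an estimated correlation. Of 9 measured chaperones 0 rose and 6 fell (0 and 6 adjusted over the list alone), such as Hspd1 (-0.59 ± 0.06), Hspe1 (-0.59 ± 0.05) and Hsp90aa1 (-0.51 ± 0.05), with a fry adjusted p of 0.0376 (0.226 with an estimated correlation). Of 33 nuclear genes of oxidative phosphorylation 12 fell (20 adjusted over the list alone), such as Cycs (-0.50 ± 0.05) and Atp5g1 (-0.34 ± 0.04), with an adjusted p of 0.0166 (0.259). Of 15 genes of the unfolded protein response 5 fell, such as Hsp90b1 (-0.37 ± 0.05) and Pdia6 (-0.34 ± 0.06), and 8 fell and 1 rose adjusted over the list alone (adjusted p = 0.0376, or 0.259). MHC class I genes rose, 7 of 13 over all genes and 10 adjusted over the list alone, such as H2-Q6 (0.55 ± 0.11) and H2-T23 (0.40 ± 0.08), with an adjusted p of 0.0396 (0.301). H2-Q6 and H2-T23 were called in A and B (0.72 and 0.46) but not in C and D (0.34 and 0.31). Of 37 S phase genes 5 fell (11 adjusted over the list alone), such as Blm (-0.56 ± 0.08), and the list was not called (adjusted p = 0.0551). Erythroid markers were mixed, with 3 of 11 higher and 2 lower (4 and 2 adjusted over the list alone), such as Mt2 (3.20 ± 0.22) and Car2 (0.65 ± 0.05), with an adjusted p of 0.0239 (0.226). Basophil or mast cell markers were called upward (adjusted p = 0.0376, or 0.635) though the median of the 6 was -0.01.

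In all 11 lists were called by fry in old MkP, and none holds with an estimated correlation between genes. HSC markers and the ageing signature come closest, and the granule genes follow. The number of lists called was 0 without A, 0 without B, 4 without C and 7 without D, and 0 with libraries summed in 2 pairs. Single genes such as Mecom, Selp and Hspe1 kept their call without any 1 library.

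Among old cells, Tom+ MkP carried more metallothionein Mt2, Rora, clusterin (Clu) and the receptor gene Chrm3 than GFP+ MkP, and less Cd48, Plac8 and Nkg7. Mt2 was higher by log2 3.22 ± 0.19, Chrm3 by 3.22 ± 0.18, Rora by 2.89 ± 0.21, Rhoj by 2.57 ± 0.25, Phactr1 by 2.55 ± 0.12, Clu by 2.51 ± 0.16, Bex1 by 2.24 ± 0.16, Selenom by 2.02 ± 0.14, Plscr2 by 2.01 ± 0.15 and Magi2 by 2.00 ± 0.19. Il1rapl2 was higher by 5.46 ± 0.43 (4.82 without B, 6.88 without C) and Rorb by 2.53 ± 0.23 (3.28 without A). Cd48 was lower (-3.23 ± 0.21), as were Clec4d (-3.12 ± 0.18), Plac8 (-2.26 ± 0.14), Cst7 (-2.12 ± 0.16), Rapsn (-1.94 ± 0.16), Atp13a3 (-1.93 ± 0.19), Nkg7 (-1.86 ± 0.08, adjusted p = 1.6e-14), Ubash3a (-1.82 ± 0.16), Fcer1g (-1.74 ± 0.14), Bin1 (-1.71 ± 0.11) and Samd14 (-1.66 ± 0.14). Slamf1 was higher in Tom+ MkP (1.06 ± 0.14, adjusted p = 4.4e-06) and so was Kit (0.54 ± 0.11). Egfp (-6.20 ± 0.12) and Tdtom (6.91 against 0.835 CPM) follow from the class itself. These genes kept their direction in 4 of 4 libraries.

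HSC markers and the ageing signature were also higher in old Tom+ than in old GFP+ MkP. Of 13 HSC markers 10 were higher and 0 lower (11 and 0 adjusted over the list alone), such as Ctnnal1 (1.65 ± 0.13), Mecom (1.63 ± 0.10) and Ifitm1 (0.86 ± 0.10), with adjusted p = 0.00284 with an estimated correlation. Of 23 ageing genes 18 were higher and 1 lower (20 and 1 adjusted over the list alone), such as Gda (1.99 ± 0.15) and Clca3a1 (1.21 ± 0.11) against Fyb (-0.38), with adjusted p = 0.0294 with an estimated correlation. Of 5 basophil or mast cell markers 4 were lower (5 adjusted over the list alone), such as Cpa3 (3.90 against 22.5 CPM), with the same adjusted p of 0.0294. Platelet receptors were lower in 9 and higher in 3 of 26, such as Itga2 (-1.60 ± 0.20), Gp5 (-0.79 ± 0.12) and Syk (-0.52 ± 0.08), with a fry adjusted p of 0.0374 that does not hold with an estimated correlation (0.426). Of the 12 MkP markers 2 were higher, Vwf (0.86 ± 0.09) among them, and 6 lower, such as Cd9 (-0.69 ± 0.07) and Treml1 (-0.55 ± 0.12). Of 37 S phase genes 8 were lower (14 adjusted over the list alone), such as Rfc2 (-0.65 ± 0.07), while 17 of 47 G2 and M phase genes were higher (19 and 2 lower adjusted over the list alone), such as Mki67 (0.39 ± 0.08). The transcription factor Gata1 was lower (-0.88 ± 0.11). The G2 and M phase list was not called (adjusted p = 0.119).

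The Tom+ and GFP+ comparison, chosen after seeing the data, called 1430 of 10480 genes by edgeR quasi-likelihood with BH, 728 higher and 702 lower in Tom+. DESeq2 called 929, the fit without the block 742, equal numbers of cells 481, and libraries summed in 2 pairs 917. Without A 923 and without B 922 were called. Within each pair alone 271 genes were higher and 225 lower, where 31.6 and 28.4 would arise by chance, and 2 went opposite ways. The classes are drawn on the reporter, so Egfp and Tdtom are no finding here, and Cd48, Mt2 and Nkg7 are differences between cells of the same library and age. Each class holds cells of both CD150 gates. Differences between the gates, such as in Slamf1, are therefore not separated from those between the classes.

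Within GFP+ MkP, where reporter classes cannot differ, age still changed Aldh1a1, Casp12, Nupr1, Cd48 and the chaperones. Aldh1a1 rose by log2 2.63 ± 0.15 (adjusted p = 2.4e-11), Casp12 by 2.71 ± 0.23, B3galt1 by 2.01 ± 0.35, Nupr1 by 1.54 ± 0.21, Pdgfd by 1.54 ± 0.22, Clca3a1 by 1.52 ± 0.14, Arhgef28 by 1.35 ± 0.19, Aim2 by 1.28 ± 0.19 and S100a6 by 1.26 ± 0.17. Plscr2 went from 0.568 to 15.4 CPM (4.47 ± 0.36, or 5.07 without A), and Rorb rose by 3.11 ± 0.50 (2.11 without A, 4.07 without B). Magi2 (1.46 ± 0.31) lost its call without A (1.22, adjusted p = 0.086) and without B (1.28, adjusted p = 0.098). Plxdc2 fell (-2.07 ± 0.22, adjusted p = 1.5e-06), as did Cers6 (-1.29 ± 0.17), Hsph1 (-1.15 ± 0.14), Usp40 (-0.997 ± 0.15), Myo10 (-0.87 ± 0.14) and Cd48 (-0.78 ± 0.13). Bex4 (-0.86 ± 0.18) lost its call without A (-0.79, adjusted p = 0.12) and without B (-0.52, adjusted p = 0.17). Kit (0.26, adjusted p = 0.31), Slamf1 (-0.13, adjusted p = 0.79) and Egfp (-0.14 ± 0.08, adjusted p = 0.46) were not called. The named genes that were called kept their direction in 4 of 4 libraries by edgeR quasi-likelihood.

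Ageing, MHC class I, chaperone, basophil or mast cell and dendritic cell lists changed in GFP+ MkP. Of 23 ageing genes 8 rose and 1 fell (11 and 1 adjusted over the list alone), such as Mmrn1 (0.64 ± 0.11), with adjusted p = 0.0199 with an estimated correlation. Of 13 MHC class I genes 8 rose and 0 fell (12 and 0 adjusted over the list alone), such as H2-T23 (0.55 ± 0.08), with adjusted p = 0.0436 with an estimated correlation. In CD150+ MkP of both reporter classes H2-T23 was called in A and B (0.46) but not in C and D (0.31). Of 8 chaperones 6 fell (6 adjusted over the list alone), such as Hspd1 (-0.54 ± 0.07) and Hsp90aa1 (-0.51 ± 0.05), with adjusted p = 0.0392 with an estimated correlation. Of 5 basophil or mast cell markers 2 rose and 0 fell (4 and 0 adjusted over the list alone), such as Gata2 (0.39 ± 0.08), with adjusted p = 0.0199 with an estimated correlation. Of 5 dendritic cell markers 3 rose (3 and 1 lower adjusted over the list alone), such as H2-Ab1 (0.92 ± 0.16), with adjusted p = 0.0436 with an estimated correlation. HSC markers were not called there, with 2 of 13 higher, Pdzk1ip1 (0.71 ± 0.10) among them (fry adjusted p = 0.319). Of 10480 genes 221 were called, 157 higher and 64 lower, and DESeq2 called 124. With libraries summed in 2 pairs the number was 93, without A 102 and without B 78. Of the 1216 genes called in CD150+ MkP 1173 were tested here, in GFP+ cells of both gates. Of these, 1094 had the same direction, 188 were called in it and 1 in the opposite one. Since these comparisons share cells, genes called in A and B were read in the GFP+ cells of C and D, where 67.4 % had the same direction. Genes called in C and D were read in those of A and B, where 81.7 % did. The median log2, taken in the direction of the call, was 0.13 and 0.20.

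Tom+ MkP are a larger part of old than of young MkP, and the mixture of classes enters the age comparison of Cd48, Rora and every other gene that differs between them. With both gates together, Tom+ cells were 46.7 % of old MkP in A, 47.8 % in B, 47.6 % in C and 39.4 % in D. Of young MkP they were 2.82 %, 1.94 %, 21.6 % and 12.4 %. Over the 1216 called genes, each log2 value was taken in the direction of the gene's call. The change of mixture alone then gives a median of 0.127, 0.122, 0.106 and 0.0915 in the 4 libraries. Observed were 0.471, 0.492, 0.416 and 0.381, in genes chosen for their change in these same libraries. In old Tom+ MkP the HSC markers together had a median of 15.9 UMIs per 10000, between 10.3 in old GFP+ MkP and 46.9 in old HSC. MkP markers had 56.9 in old Tom+ MkP, 53.9 in old GFP+ MkP and 5.61 in old HSC. Erythroid markers had 11.3 against 5.82, basophil or mast cell markers 1.90 against 2.20 and granulocyte markers 2.49 against 2.64 in old Tom+ and GFP+ MkP. The ageing signature had 22.97 in old Tom+ MkP, 12.2 in old and 8.56 in young GFP+ MkP, 19.4 in old HSC and 4.55 in young HSC.

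Among HSC, the number of young cells allows only a glance at genes such as Nupr1 and Egfp. There were 172 old but 17 young HSC, so the planned fit was not possible. In CD150+ HSC, Nupr1 stood at 276 CPM in old (95 % limits 254 to 298) and 33.4 in young (12.2 to 72.7). Egfp stood at 263 against 1463 CPM. Rorb had 171 UMIs in old and 0 in young HSC, and Clca3a1 158 and 0, where 0 UMIs allow up to 20.5 CPM. A small fit chosen after seeing the data (A and B, sums of at least 5 cells) called 33 of 7072 genes by edgeR quasi-likelihood with BH, with 424 at an unadjusted p under 0.05 and 0 by DESeq2. It has Nupr1 (3.12, adjusted p = 1.7e-06) and Pdgfd (1.95, adjusted p = 0.0225) higher, and Egfp (-2.24, adjusted p = 3.7e-14), Plac8 (-1.42, adjusted p = 0.0225) and Plxdc2 (-1.39, adjusted p = 0.0342) lower in old HSC.

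Old MEP shared several of these changes. S100a6 rose by log2 2.54 ± 0.27, Aldh1a1 by 1.91 ± 0.16 (adjusted p = 8.1e-09), Casp4 by 1.57 ± 0.20, Cd34 by 1.35 ± 0.19 and Mecom by 1.26 ± 0.18. Plxdc2 (-2.15 ± 0.23), Trib2 (-1.38 ± 0.15), Grb10 (-1.06 ± 0.20), the carbonic anhydrase Car1 (-0.89 ± 0.09) and Myb (-0.44 ± 0.08) fell. Of 10 MkP markers 4 rose and 0 fell (5 and 0 adjusted over the list alone), such as Rap1b (0.63 ± 0.10), and of 21 platelet receptor genes 5 rose and 0 fell (6 and 0 adjusted over the list alone), such as Tbxas1 (0.86 ± 0.15), each with a fry adjusted p of 0.0316 that does not hold with an estimated correlation (0.0759). Of 13 erythroid markers 2 fell (5 adjusted over the list alone). By edgeR quasi-likelihood 282 of 9735 genes were called in MEP (184 higher, 98 lower), against 37 by DESeq2, 104 without A and 170 without B. The named genes kept their direction in 4 of 4 libraries.

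The age effect in CD150+ cells differed between MkP and other types for genes such as Cd48, Mt2, Plac8 and Egfp. Against MEP 169 genes differed (74 more positive, 95 more negative in MkP), such as Zg16 (2.33 ± 0.29) and Grb10 (2.02 ± 0.24) against Cd48 (-1.32 ± 0.19) and Egfp (-1.10 ± 0.12, adjusted p = 3.5e-06). Against early erythroid progenitors A 110 differed (69 and 41), such as Mt2 (3.35 ± 0.40), Cited4 (1.99 ± 0.30) and Cd24a (1.74 ± 0.21) against Csrp3 (-2.86 ± 0.31), Plac8 (-1.82 ± 0.24) and Samd14 (-1.30 ± 0.17). Against Other Myeloid cells 90 differed (48 and 42), such as Mt2 (3.71 ± 0.35, 2.92 without B) and Bex4 (3.38 ± 0.36) against Plac8 (-1.49 ± 0.20). Against early erythroid progenitors B 99 differed, and there 5 of 23 ageing genes were more positive in MkP (11 adjusted over the list alone, fry adjusted p = 0.014, or 0.0937 with an estimated correlation). These differences were chosen after seeing the data and tested by edgeR quasi-likelihood with BH. Their counts fall to 69, 14, 16 and 24 without A and to 42, 38, 8 and 23 without B, in the order MEP, early erythroid progenitors A, Other Myeloid and early erythroid progenitors B. Without C and without D the count against MEP is 97 and 86, and without D that against Other Myeloid is 142.

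Of the 17 types with a fit, Cenpv and the cold-shock gene Rbm3 rose with age in 16 each. The median log2 over the types called was 0.99 for Cenpv and 0.39 for Rbm3. Tnfsf13 rose in 14 types (1.41), but the gene Tnfsf13os overlaps it on the other strand and was also called in 14, so the source of these reads is uncertain. H2-Ab1 rose in 12 types (1.10), Pbx3 in 12 (0.86), Aldh1a1 in 9 and the cold-shock gene Cirbp in 9 (0.55). Hmga2 fell in 11 types (-1.51), Lgals1 in 10 (-0.99), Egfp in 10 (-0.44), Ifi27l2a in 9 (-1.89) and Plxdc2 in 7. Types differ in cells per sum, and calls of most types depend on A and B.

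In old mice Aldh1a1 was called higher and Lgals1 lower in every erythroid type but Ery D, and Fabp5 and Cpd lower in every one but early erythroid progenitors A. In early erythroid progenitors A Csrp3 rose by log2 2.00 ± 0.22, Ifi47 by 1.42 ± 0.18 and Aldh1a1 by 1.31 ± 0.13, and Lgals1 (-1.15 ± 0.13), Bex4 (-0.99 ± 0.13) and Hist1h1b (-0.86 ± 0.11) fell. In early erythroid progenitors B Aldh1a1 rose (1.07 ± 0.10), and Lgals1 (-0.99 ± 0.09) fell. Ery A cells, whose old sums come from C and D only, gained Aldh1a1 (1.11 ± 0.13) and lost Lgals1 (-1.38 ± 0.14) and Fabp5 (-1.09 ± 0.07), and Ery B cells, with enough cells in C and D only, gained Pbx3 (0.87 ± 0.06) and lost Cpd (-1.41 ± 0.12) and Fabp5 (-1.21 ± 0.05). Ery C cells lost Cpd (-1.45 ± 0.06), Fabp5 (-1.27 ± 0.04) and Lgals1 (-1.25 ± 0.07), and Ery D cells lost Fabp5 (-1.48 ± 0.15) and Cpd (-1.28 ± 0.13). By edgeR quasi-likelihood with BH, 404 genes were called in early erythroid progenitors A, 1034 in B, 433 in Ery A, 230 in Ery B, 1156 in Ery C and 27 in Ery D. Without A the counts were 126 in early erythroid progenitors A, 131 in B and 19 in Ery C, without B 107, 167 and 21, without C 169 in Ery A and 184 in Ery D, and without D 266 in early erythroid progenitors A, 263 in Ery A, 2693 in Ery C and 233 in Ery D. Ery D had 220 without B.

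The sum of MHC class I genes was higher in old than in young erythroid cells of A and B, while in C and D only single members were called, some higher and B2m lower (-0.24 in Ery C and -0.15 in early erythroid progenitors A). A rise in A and B is also seen outside these types, with 5390 against 3282 CPM in Other Myeloid cells of A and B (3004 and 3228 in C and D) and 3511 against 2537 in GMP/Neut progenitors A (2589 and 2482). In Ery C the 13 genes together stood at 3740 CPM in old and 1148 in young cells of A and B, against 1100 and 1205 in C and D. Early erythroid progenitors A had 4678 and 2408 CPM in A and B, and 2096 and 2312 in C and D. In early erythroid progenitors B all 13 genes rose in the fit over all libraries (13 adjusted over the list alone, median 0.92, fry adjusted p = 0.0325, or 0.226 with an estimated correlation), although C and D had 1871 in old and 1984 in young. Psmb8 in Ery C (2.90 ± 0.26) lost its call without A (2.02, adjusted p = 0.48), as did Psmb9 (2.77 ± 0.20; 2.06 and 0.36 without A) and Ifi47 (2.36 ± 0.11; 1.88 and 0.14), by edgeR quasi-likelihood. Without B they lost it too (2.10, 2.08 and 1.96). In MkP the sums were 3837 against 3003 CPM in A and B and 3333 against 3014 in C and D.

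**Figure D4:**
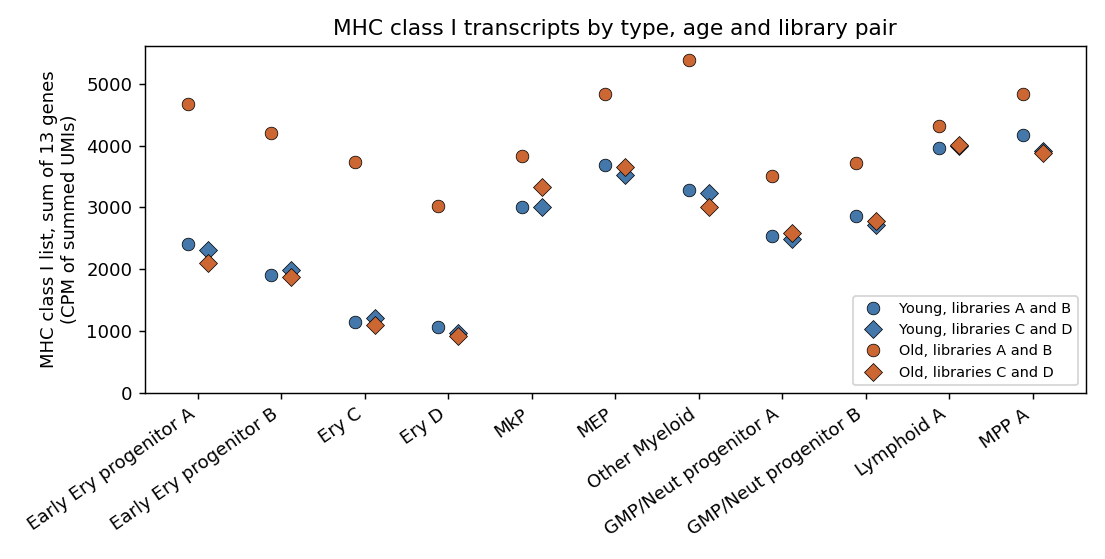
Sum of 13 MHC class I genes (CPM) per cell type, age and library pair (A and B, C and D). Old Ery C cells of A and B stand at 3740 CPM, those of C and D at 1100.

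Myeloid and multipotent progenitors gained Cenpv with age. GMP/Neut progenitors A gained Cenpv (1.21 ± 0.09) and Ifitm1 (1.03 ± 0.10) and lost Trim30a (-0.68 ± 0.06), with 122 genes called by edgeR quasi-likelihood (29 without A, 56 without B, 71 without C and 53 without D). GMP/Neut progenitors B gained Mrgpra2b (1.23 ± 0.08) and Cenpv (1.20 ± 0.08) and lost Apoe (-0.79 ± 0.09), with 97 called (59 without A, 38 without B). Other Myeloid cells gained Aldh1a1 (2.34 ± 0.29, 1.75 without B and 3.39 without D), with 84 called (20 without A, 15 without B). MPP A gained B3galt1 (2.96 ± 0.29), Il1rapl2 (2.20 ± 0.30) and H2-Eb1 (2.07 ± 0.29) and lost Plxdc2 (-1.76 ± 0.24), Hmga2 (-1.70 ± 0.15) and Isg15 (-1.64 ± 0.22), with 76 called (34 without A, 20 without B, 33 without D). MPP B gained Cenpv (1.05 ± 0.14) and H2-Ab1 (1.03 ± 0.14) and lost Ifi27l2a (-1.67 ± 0.18) and Hmga2 (-1.52 ± 0.12), with 45 called (28 without A, 23 without B, 69 without D). MPP D had 15 called (48 without A, 25 without B, 40 without C and 1 without D). In GMP/Neut progenitors A 5 of 19 type I interferon genes fell (13 adjusted over the list alone, median -0.51, fry adjusted p = 0.0374, or 0.117 with an estimated correlation).

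Lymphoid types lost Hmga2 and Ifi27l2a and gained Cenpv. Lymphoid B cells gained Cenpv (1.36 ± 0.13), Otos (1.24 ± 0.17) and H2-Ab1 (1.06 ± 0.14) and lost Ifi27l2a (-2.36 ± 0.22), Ly86 (-1.77 ± 0.24), Hmga2 (-1.37 ± 0.17) and Flt3 (-0.58 ± 0.09, adjusted p = 5.1e-05), each in 4 of 4 libraries. Markers of other cell types moved there as well. Of 8 basophil or mast cell markers 4 rose and 0 fell (6 and 0 adjusted over the list alone), and of 7 lymphoid progenitor markers 0 rose and 5 fell (0 and 7), with a fry adjusted p of 0.0525 each, just short of a call. A change in which cells make up the type is thus not separated from a change within cells. Of 14 type I interferon genes 7 fell there and 0 rose (8 and 0 adjusted over the list alone, fry adjusted p = 0.029, or 0.0472 with an estimated correlation). Lymphoid A cells gained H2-Aa (2.31 ± 0.35), Arhgef28 (1.65 ± 0.26) and Cenpv (1.35 ± 0.21) and lost Plxdc2 (-2.06 ± 0.29, -2.74 without D) and Ifi27l2a (-1.53 ± 0.18). Lymphoid C cells gained Ncam1 (1.83 ± 0.24) and Cenpv (1.29 ± 0.11) and lost Hmga2 (-1.76 ± 0.16). The basophil or mast cell marker Cpa3 fell there (-0.49 ± 0.07) though it rose in Lymphoid B (0.75 ± 0.07). The lymphoid progenitor marker Dntt fell as well (-1.61 ± 0.34), so the same caution on which cells make up the type holds for Lymphoid C. By edgeR quasi-likelihood 152 genes were called in Lymphoid B (86 without B, 100 without D), 95 in Lymphoid A (261 without B, 33 without C, 5 by DESeq2) and 34 in Lymphoid C (22 without A).

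CD150+ Ery A cells carried far fewer globin transcripts than CD150- Ery A cells, and CD150+ early erythroid progenitors carried more Gmfg, Apoe and Mef2c. Slamf1 itself was higher in CD150+ Other Myeloid cells (log2 1.85 ± 0.28, adjusted p = 3.6e-05), in early erythroid progenitors A (1.76 ± 0.29, adjusted p = 0.0014; 1.43 and 0.09 without A, 1.70 and 0.06 without B) and in B (1.44 ± 0.26, adjusted p = 0.0039; 1.33 and 0.072 without A, 1.57 and 0.059 without B), but not in Ery A (-0.26 ± 0.36, adjusted p = 0.65). Early erythroid progenitors A of the CD150+ gate had more Nkg7 (0.91 ± 0.13), Gmfg (0.79 ± 0.10), Apoe (0.72 ± 0.08) and Mef2c (0.68 ± 0.09) and less Jund (-0.58 ± 0.08), Mt2 (-0.47 ± 0.06) and the transferrin receptor Tfrc (-0.45 ± 0.08). Ery A cells had more Gmfg (2.49), Apoe (2.42), Ramp1 (2.19) and Kit (0.79 ± 0.08) and less of the globins Hba-a2 (-5.21 ± 0.18) and Hbb-bt (-4.68), and 14 of 15 erythroid markers were lower there and 1 higher (14 and 1 adjusted over the list alone). Other Myeloid cells had less Lmo4 (-1.84), Ifitm1 (-1.19), Cpa3 (-1.07), Jun (-1.05) and Cd63 (-1.01). By edgeR quasi-likelihood with BH, 105 genes were called in early erythroid progenitors A, 1467 in B, 2708 in Ery A and 63 in Other Myeloid cells. Without A these were 32 and 93 in the first pair of types and 35 in Other Myeloid, without B 40, 100 and 16, and Ery A had 1208 without C and 1233 without D. With libraries summed in pairs early erythroid progenitors B had 0 calls by edgeR, with 2242 genes at an unadjusted p under 0.05.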

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

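Single values of a group of 4 libraries were compared with the other 3 by Dixon's ratio, and chance alone gives such a value in about 1 in 20 groups. Of 232 groups tested, 14 had one. Old MPP D cells without an Egfp UMI made up 15.38 % in library C, and old Other Myeloid cells 18.75 % in D. In CD150+ MkP, Phactr1 stood at 96.74 CPM in old B, Nupr1 at 5.765 in young D and Atp13a3 at 7.493 in old C. In Tom+ and GFP+ MkP of old mice, Il1rapl2 stood at 7.475 CPM in GFP+ cells of C, Egfp at 5.9 in Tom+ cells of C and Nkg7 at 113.1 in Tom+ cells of D. In GFP+ MkP, Clca3a1 stood at 34.42 CPM in old D, Aim2 at 18.61 in young B, Plxdc2 at 14.69 in old B, Cers6 and Myo10 at 11.21 each in old C, and Snx25 at 14.95 in old C. None of these values was left out of a fit.

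Age effects differed between cell types and between library pairs. MkP differed from MEP in 169 genes, from early erythroid progenitors A in 110, from early erythroid progenitors B in 99 and from Other Myeloid cells in 90. For each MHC class I gene the age effect in C and D was subtracted from that in A and B. The median difference over the genes was log2 1.111 in early erythroid progenitors A, 1.596 in early erythroid progenitors B and 1.684 in Ery C. It was 1.564 in Ery D, 0.4877 in GMP/Neut progenitors A and 0.3528 in GMP/Neut progenitors B. These are the types in which the list differed with an adjusted p under 0.05. Other Myeloid cells had 0.7851 and an adjusted p of 0.05395, with 5 of 13 genes called. Over the types tested, 3414 gene calls of a different age effect between the pairs were made. These tests of pairs, of lists and of genes, use the spread between libraries of the same pair. If a pair is 1 divided pool, they cannot tell such a difference from ordinary variation between pools or mice. The 188 barcodes without annotation were looked at only as totals, and the 413 Tdtom UMIs of the matrix only between reporter classes.

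The tests of the rise of GFP-negative MkP were chosen only after the result was seen, except the thinned comparison, which was planned. Less reporter switching in every old cell type could raise this share. HSC aside, MkP gained at least 14.31 points more GFP-negative cells than any other type in each library. As a logit, however, the gain of MkP is the largest in A and B (3.297 and 3.615) but not in C (1.17, against 1.877 in Ery D) or D (1.491, against 3.225 in MPP A). By the authors' GFP group HSC gained 47.33 points with the cells of all libraries pooled, from 17 young cells, against 38.42 in MkP. Counted as cells without an Egfp UMI, the order is the other way round, with thinning and without it. After thinning the rise is from 33.33 to 63.25 % in HSC and from 6.818 to 41.27 % in MkP. Without thinning it is from 29.41 to 49.42 % in HSC and from 6.5 to 29.33 % in MkP. Less switching therefore stays open, in all types or in HSC alone. HSC counted as MkP could also raise it. However, genes at least 4 times higher in HSC imply a share of HSC transcripts in old Tom+ MkP of 10.4 % at the median and 20.34 % at the upper quartile of 151 genes. For 6 of these genes the share is over 50 %. A share of cells would be higher, since old CD150+ HSC have a median of 14010 UMIs and old CD150+ MkP 24399. The level of 8 MkP markers, at a median of 93.8 % of that in old GFP+ MkP (Gp5 64.09 %, Rap1b 113.6 %), adds little. All these cells were annotated as MkP, so high MkP markers are in part set by the annotation. Shallower old cells might hide Egfp, but with all cells thinned alike the gain is 34 points (SD 5.975, from 27.05 to 40.23 over the libraries). The rise is therefore not put down to depth, and by the median gene HSC do not make up most of old Tom+ MkP. Some HSC among them are not excluded, since the shares are averages over all these cells. Free RNA, mice per pool and the age of the switch were not tested.

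All tests of the MHC class I rise in old erythroid cells of A and B were chosen only after the result was seen. RNA or cells of another type might carry these transcripts, but marker genes of the other types imply at most 1.771 % of the share that the rise would need, wherever at least 10 such genes exist. Other Myeloid cells in early erythroid progenitors A, with 6 such genes, were not tested. A different maturation stage could shift the level, but the lowest old erythroid type of A and B still has 1.257 times the level of the highest young one. Young MEP of A and B, left out of that test, stand at 3691 CPM. Old cells there have 3028 in Ery D, 3740 in Ery C, 4198 in early erythroid progenitors B and 4678 in A. The test therefore covers stages among the erythroid types and not a shift toward MEP. Early erythroid progenitors A keep the difference between the pairs in 11 of 13 genes, and early erythroid progenitors B in 13. An event in the old mice of 1 experiment, such as an infection, remains possible and cannot be told from age with these libraries.

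Counts of calls were compared with those after swapping old and young labels within libraries, a test written before the results were seen. With 8 ways to swap (4 where 3 libraries are left), the true labels are 1 of the splits, so a share under 0.05 could not be reached, and in every comparison only 1 split, the true one, gave as many calls. For MkP the true labels gave 1216 calls and the highest other split 0, and for Tom+ against GFP+ MkP these were 1430 and 3, and for GFP+ MkP 221 and 2. MEP gave 282 against 2, GMP/Neut progenitors A 122 against 3, B 97 against 2, Lymphoid A 95 against 2 (4 splits), Lymphoid B 152 against 7, Lymphoid C 34 against 8, MPP A 76 against 6, MPP B 45 against 5 and MPP D 15 against 8 (4 splits). Early erythroid progenitors A gave 404 against 94 and B 1034 against 381, where the highest other split swaps A and B against C and D, and Ery C gave 1156 against 395 (4 splits), likewise with A and B against D. Ery D gave 27 against 3 (4 splits). The gate gave 105 against 1 in early erythroid progenitors A and 1467 against 0 in B. Differences between MkP and MEP gave 169 against 0, early erythroid progenitors A 110 against 0, early erythroid progenitors B 99 against 1 and Other Myeloid 90 against 1.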

How the results depend on the processing

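The main counts were compared with those under other settings, and a count is said to move when it changes more than 1.5-fold. Values are given in the order old against young MkP (1216 calls), Tom+ against GFP+ MkP (1430), old against young GFP+ MkP (221), the 16 other types together (4286), the gate (4343) and differences of effects (468). DESeq2 called 474, 929, 124 and 2490 in the first 4 and did not move the others. No filter on low counts gave 380 for GFP+ MkP, 7962 for the other types and 1324 for differences. With no replicate block the counts were 508, 742, 69, 668, 1724 and 152, each lower. Equal numbers of cells per sum gave 199, 481, 39, 1222, 1385 and 68. Leaving out 1 library gave 646 to 1158, 922 to 1267, 78 to 222, 1528 to 5542, 2868 to 2951 and 111 to 423, with the lowest counts in most cases without A or B. Libraries summed in 2 pairs gave 917 for Tom+ against GFP+ MkP, 93 for GFP+ MkP, 1968 for other types, 2236 for the gate and 76 for differences. A and B only gave 416, 9925 and 1598 for GFP+ MkP, other types and differences, and C and D only gave 498, 878, 94 and 141 for MkP, Tom+ against GFP+, GFP+ MkP and differences. For each of these changes the cause was not tested.

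The share test called 5 types in the CD150+ gate, 2 with no replicate block, 3 with TMM scaling of cell numbers, 1 without any 1 library, 1 with libraries summed in pairs and 2 in C and D only. The MkP ratio was 1.446 to 1.988 with 1 library left out and 1.711 with pairs, no longer past the threshold in either case. In the CD150- gate 0 types were called, 3 with TMM scaling, 0 to 1 with 1 library left out, 12 in A and B only and 9 in C and D only. There HSC (3 young cells over all libraries) reached 3.121 and MkP 1.856 in A and B only. MEP turned to -1.272 in C and D only. Calls within 1 pair measure only the spread between its libraries. The 11 list calls in old MkP became 0 with an estimated correlation, 6 with no filter, 2 with no replicate block, 4 with equal numbers of cells, 0 to 7 with 1 library left out, 0 with pairs and 0 in C and D only. The reporter difference of MkP (-2.474) stayed at -2.81 to -2.012 with 1 library left out. Of single genes, 957 gene and comparison combinations gave 11434 values, of which 9939 stayed on the same side of the threshold, 1304 were no longer past it and 186 newly past it. Turned in sign were Egfp in early erythroid progenitors A (0.1775 in A and B only), Kit in Ery C (-0.05239 with no replicate block), Hells in MEP (-0.06933 with equal cells), Ect2 in MkP (0.1128 with equal cells) and Pf4 in Tom+ against GFP+ MkP (0.07755 in A and B only). Sums per aliquot, the planned HSC fit and the difference between MkP and HSC were not run.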

Other observations

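Fcer1a, which encodes the alpha chain of the IgE receptor, was almost absent from young and present in old MEP and GFP+ MkP. It stood at 36.2 CPM in old against 0.264 in young MEP, and at 19.5 against 0.780 in GFP+ MkP, with adjusted p = 1.5e-10 and 6.9e-07 by edgeR quasi-likelihood, in 4 of 4 libraries of the latter. Old Tom+ MkP had less of it than old GFP+ MkP (7.53 against 19.5 CPM). Lyz2 (log2 1.18 ± 0.13), Prtn3 (1.19 ± 0.11) and Cpa3 (0.77 ± 0.13) also rose in old MEP. The fixed lists of granulocyte and of basophil or mast cell markers were not called there (fry adjusted p = 0.0681 and 0.0708). Slamf1 and Cd48 lie next to each other on chromosome 1 (from 171767127 and from 171682009), yet Tom+ MkP have more Slamf1 (1.06 ± 0.14) and less Cd48 (-3.23 ± 0.21) than GFP+ MkP. Each class there holds cells of both gates.

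The erythroid types Ery B and Ery C divide the libraries almost fully. Ery C has 95.1 % of its cells in A and B, Ery B 0.205 %, Ery A 8.53 % and Ery D 50.1 %. Ery B and Ery C thus hold cells of different library pairs, and their age effects on Fabp5 (-1.21 ± 0.05 and -1.27 ± 0.04) and Cpd (-1.41 ± 0.12 and -1.45 ± 0.06) are alike. Whether they are 1 type separated by the annotation was not tested. Of further genes called in many types, Rnf220 fell in 13 and Ifi27 in 10, and AW112010 rose in 12, Aspa in 9 and Otos in 9.

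A temperature difference in handling is a hypothesis for part of the shared age effects, and its test was chosen only after the result was seen. If old cells had been kept colder or young cells warmer, cold-shock genes would be higher and chaperones lower in old cells of every type. Rbm3 was higher in all 17 types (log2 0.16 to 0.63, called in 16), Cirbp was higher in 17 (called in 9), and the chaperone median was lower in 17 (-0.51 to -0.04). No chaperone was called lower in 8 of the 17 types, however, and in 3 types a chaperone was called higher. Rbm3 and Cirbp were taken from the genes called in many types, so their agreement was fixed beforehand, and these values cannot tell handling from a difference between the mice. Sorting order or time on ice is not given in the labels, and Hsph1 and Hspd1 should therefore be read with care.

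The hypothesis can be tested on new cells. Marrow of young and old mice would be kept side by side on ice and at room temperature for the same time, with sorting in both orders, and Rbm3, Cirbp and Hsph1 measured in MkP. A gap between ages that vanishes with equal handling would put these 3 genes down to handling. For the reporter, GFP-negative and GFP+ MkP of young and old mice of several litters, 1 mouse per library, would show whether the 34 points of gain hold between mice.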
